A study of Homo sapiens with 21 samples.

How the data were processed

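Messenger RNA was measured in 21 libraries of 2 human leukaemia cell lines. Per the labels, 18 libraries came from OCI-AML3, an acute myeloid leukaemia line, and 3 from K562, a line from a chronic myeloid leukaemia in blast crisis. The labels place them in 7 groups of 3 libraries and 2 sequencing batches. Batch 1 held OCI-AML3 parental cells, OCI-AML3 cells kept with DMSO vehicle, OCI-AML3 cells labelled resistant to StAMP (biological replicate 1, "resistant 1" here) and K562 parental cells. Batch 2 held vehicle, resistant 1 and a second resistant biological replicate ("resistant 2"). The labels do not spell out StAMP, and the title speaks of stapled peptides. How the cells were grown, treated and selected is not given in the sources used here.

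Per the submitters' notes, total RNA was isolated with a Qiagen kit, strand-specific mRNA libraries were made from it, and paired reads were sequenced on an Illumina NovaSeq6000. The authors deposited gene counts, 1 table per batch, as raw counts per gene symbol with no normalization. Per the submitters' processing notes, reads were aligned to hg38, counts were obtained within the VIPER pipeline, and differential expression used DESeq2 1.22.1. The table names mention STAR gene counts. The aligner version, the annotation and the strand setting are not given in the sources used here. The values were checked and all were whole numbers of at least 0. Both tables held 28008 genes, and 0 columns were left without a sample.

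Total counts per library, in mega counts (M), ran from 14.1 to 21.1 M in batch 1 and from 30.7 to 51.3 M in batch 2. The 10 most abundant genes took 4.08 to 5.13% of the counts in batch 1 and 4.31 to 5.74% in batch 2. Positions came from the GENCODE annotation of hg38 and were matched by symbol for 24575 genes and by an older symbol for 785, which gives 25360 of the 28008. Whether the authors counted on the same annotation is not given in the sources used here.

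Differential expression used edgeR 4.0.16 in R 4.3.3, with TMM normalization, the filterByExpr low-count filter, robust quasi-likelihood fits of group means, quasi-likelihood F tests (two-sided) and Benjamini-Hochberg adjustment over the genes tested. A gene was called when its adjusted p was under 0.05. The 3 OCI-AML3 groups of batch 1 were fitted together, as were the 3 groups of batch 2. Resistant 1 was also compared with vehicle over both batches with batch as a term, and an interaction term tested whether its fold change differed between batches. K562 was compared with the OCI-AML3 parental libraries in a fit of those 6 libraries. Shared resistance genes were those called with the same sign in all 3 comparisons of resistant and vehicle libraries. These 8 comparisons, the tests, the gene lists, the fixed genes and the naming rule were chosen before the data were examined. A comparison of resistant 1 with K562 parental in batch 1 and the profile comparisons with K562 were chosen after seeing the data. Replicates are not stated to be separate cultures, so p-values measure the spread between these libraries.

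Genes were named by rule. For resistance, they were called with the same sign in all 3 comparisons with vehicle, averaged at least 10 CPM (counts relative to the TMM-scaled library size) in the higher group and did not overlap between replicates of the groups. The 10 higher and 10 lower with the greatest smallest change of the 3 were taken. In the other comparisons the 8 higher and 8 lower with the greatest change under the same conditions were named. Up to 2 members with the greatest rise and 2 with the greatest fall of a described list, and 20 fixed genes of sterol metabolism and inflammatory signalling, were also available, of which some are not reported here. CPM in the text are scaled within each fit, and in the plot of genes by library within each batch. Sex-linked marker genes, clone-based names, noncoding families and pseudogenes were counted but not named, with UCA1 passing the rule. Where all libraries of a group had 0 counts, the fold is a lower bound against 3 counts over the group's libraries. With 1 to 3 counts the ratio is given with an exact 95% counting interval. These bounds and intervals cover counting error only.

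Of 38 gene lists, 37 had at least 5 members tested, and the list of mitochondrially encoded genes had 0 members in the tables and could not be tested. The other lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with the preset inter-gene correlation of 0.01, a competitive test against the remaining genes, and adjusted by Benjamini-Hochberg over the lists of a comparison. Each call was repeated with an estimated correlation. Correlations of libraries used log2 of CPM plus 1 over 10784 genes averaging above 5 CPM.

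The fits were tested on simulated data with unchanged groups and changed genes of known fold. Few genes were changed in each simulation, as many up as down. In the real comparisons of resistant with vehicle libraries most genes were called, and scaling under so wide a change was not simulated. In the design of resistant 1 against vehicle in batch 1, 51 of 67 changes of 1.5-fold, 54 of 67 of 2-fold and 64 of 66 of 4-fold were recovered, with 10 false calls among 179. In the batch 2 design 10, 42 and 62 were recovered, with 3 false calls among 117. The interaction recovered 24, 47 and 61, with 5 false calls among 137, the joint fit 32, 60 and 64, with 7 among 163, and the design of K562 against OCI-AML3 51, 55 and 63, with 22 among 191. A simulated 1.5-fold shift of an interferon list was found with 1 other list called among 37.

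Whether the sample numbers pair the libraries was checked from the residual correlations of libraries with the same number. These ran from -0.357 to 0.391 over 11 pairs of groups. In 2 pairs of groups all 3 exceeded 0.1. These were vehicle and resistant 1 of batch 2 (0.214, 0.267 and 0.221) and resistant 1 and resistant 2 of batch 2 (0.294, 0.391 and 0.157). Vehicle and resistant 2 of batch 2 had 0.084, 0.211 and 0.155. The chi-square per gene between replicates was 1.81 to 7.18 in batch 1 and 20.8 to 84.5 in batch 2, so no library duplicated another of its group. The alternatives tried were RLE normalization, no low-count filter, DESeq2 1.42.0, the sample number as a block, other sets of libraries in the fit, each replicate left out in turn, an estimated inter-gene correlation and the self-contained test fry. Removal of trends on GC content and transcript length, and thinning of batch 2 to the depth of batch 1, were added after seeing the data. Sequence reads, splicing and genotypes were not analysed here.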

Results

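Gene expression was measured by mRNA sequencing in 21 libraries, 3 in each of 7 groups. In batch 1, total counts, in mega counts (M), were 14.7 to 17.04 M in OCI-AML3 parental, 15.2 to 21.1 M in OCI-AML3 vehicle, 14.1 to 20.1 M in resistant 1 and 14.6 to 19.0 M in K562 parental libraries. In batch 2 they were 36.1 to 51.3 M in vehicle, 30.7 to 49.6 M in resistant 1 and 41.4 to 43.7 M in resistant 2 libraries. All libraries called resistant here are named so from their labels. Every adjusted p of a gene below is from edgeR quasi-likelihood tests with Benjamini-Hochberg adjustment, and every adjusted p of a list is from camera.

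The libraries fell into 2 kinds of profile, and the 9 libraries labelled resistant sat with K562. Pearson correlations across 10784 genes of resistant 1 in batch 1 were 0.978 to 0.980 with K562 parental and 0.507 to 0.510 with the vehicle libraries of the same batch. In batch 2 the libraries of resistant 1 and resistant 2 had correlations of 0.901 to 0.940 with K562 parental, which was sequenced in batch 1, and of 0.553 to 0.576 with vehicle of their own batch. The parental and vehicle OCI-AML3 libraries of batch 1 had 0.984 to 0.987 with each other, and vehicle libraries of the batches had 0.948 to 0.960. K562 parental and OCI-AML3 parental libraries had 0.532 to 0.538. Genes are not independent replicates, so these correlations carry no test. Among 304 genes seen in OCI-AML3 but not in K562, the summed level was 0.103 to 0.110% of vehicle in resistant 1 of batch 1, 0.135 to 0.170% in resistant 1 of batch 2 and 0.130 to 0.227% in resistant 2. K562 parental libraries, by whose low counts these genes were chosen, held 0.0301 to 0.0348%. Single genes held more than the sum, as NOD2 (1.003 against 1.604 CPM) and MYO1G (3.54 against 111.9 CPM) did in resistant 1 of batch 2. Among 249 genes seen in K562 but not in OCI-AML3, the groups labelled resistant held 105 to 107%, 82.0 to 87.0% and 87.7 to 89.9% of the K562 level. That level is of batch 1, so a difference between batches may enter the shares of resistant 1 and resistant 2 of batch 2.

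**Figure D1:**
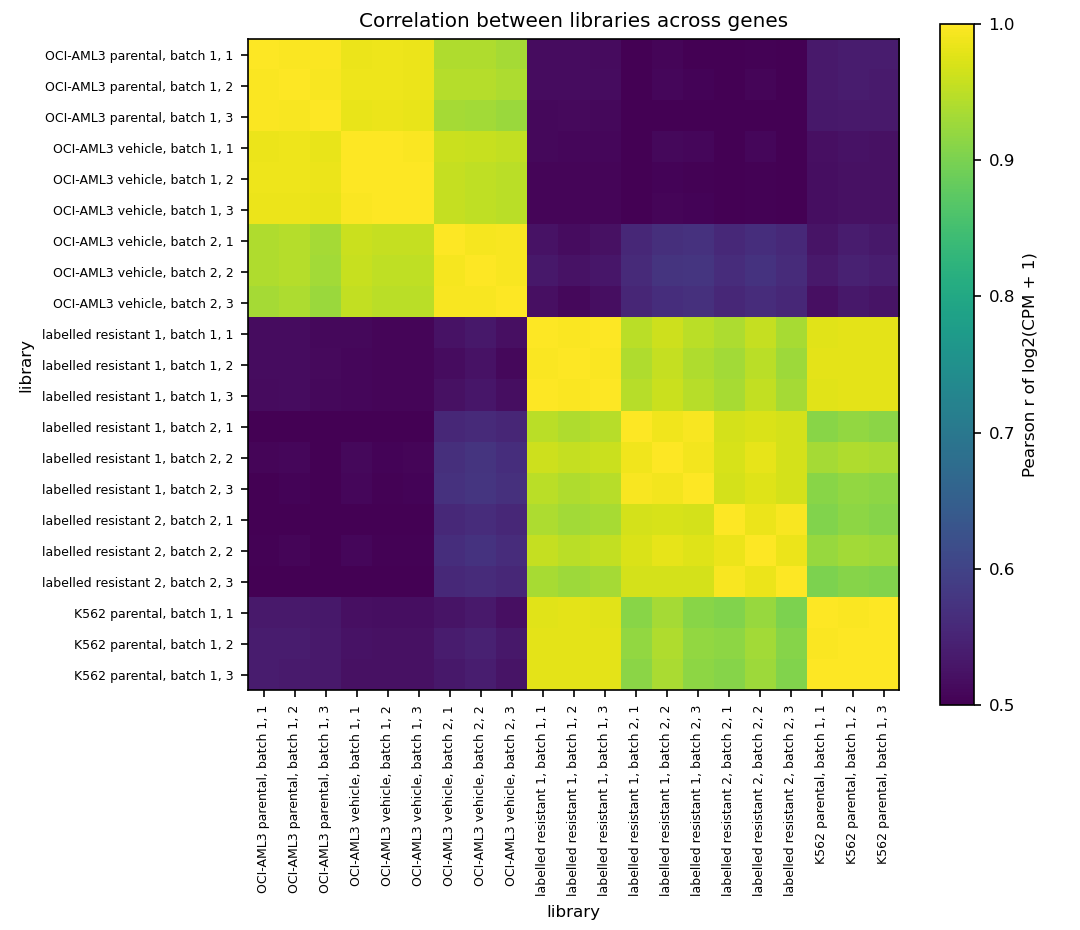
Heat map of Pearson correlations of log2(CPM + 1) across 10784 genes between all 21 libraries, ordered by group. The 9 libraries labelled resistant have 0.901 to 0.980 with K562 parental and 0.507 to 0.576 with the vehicle libraries of their own batch.

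Resistant 1 against vehicle in batch 1 asks how cells labelled resistant to StAMP differed from cells kept with DMSO. Most of the genes tested differed. As lists, red cell genes were higher in resistant 1, and monocyte, neutrophil and interferon gamma genes were lower (adjusted p = 0.00768148 to 0.0425788 with an estimated correlation). Inflammasome and cytokine genes were called lower and cholesterol biosynthesis genes higher, and these calls were lost with an estimated correlation (adjusted p = 0.249713, 0.0629175 and 0.0900998). Of 14505 genes tested, 6380 rose and 6100 fell, in all 12480, and 6459 of these changed by an absolute log2 fold change of 1 or more.

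The genes that were highest in resistant 1 had few or no counts in vehicle libraries. RHAG, a Rh-associated glycoprotein of the red cell membrane (hg38 chromosome 6, 49605175 to 49636839), averaged 497 ± 17.2 CPM (SD, n = 3) in resistant 1 and had 0 counts in vehicle, at least 8966-fold higher (adjusted p = 1.9810e-28). HEMGN, a nuclear protein of blood-forming cells (chromosome 9, 97926791 to 97944856), reached 450 ± 23.3 CPM, at least 8113-fold higher. NCKAP1, a subunit of the WAVE actin-regulating complex (chromosome 2, 182909115 to 183038858), reached 257 ± 15.6 CPM, at least 4637-fold higher. The fetal globin gene HBG2 (chromosome 11, 5253188 to 5505605) reached 1283 ± 13.5 CPM against 2 counts in vehicle, a ratio of 34650 with a 95% counting interval of 9592 to 286125, and reads can be shared with its paralog HBG1. DCAF4L2 was at least 3157-fold higher, OR51B5 at least 3116-fold, the neuropeptide gene NMU at least 2754-fold, the noncoding RNA UCA1 at least 2509-fold, the caveola gene CAVIN2 at least 2369-fold and the cancer-testis antigen gene MAGEA3 at least 2045-fold. OR51B5 (chromosome 11, 5303444 to 5505652) overlaps the annotated span of HBG2 on the same strand, so its counts may not be separate from those of HBG2. MAGEA3 had the greatest adjusted p of the 20 genes named here and in the next paragraph, 5.2214e-25.

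The genes that were lowest in resistant 1 included a myeloid regulator and homeobox genes. IRF8, a transcription factor of monocyte and dendritic cell development (chromosome 16, 85899116 to 85922606), averaged 1117 ± 15.4 CPM (SD, n = 3) in vehicle and had 3 counts in resistant 1, a ratio of 19694 with a 95% counting interval of 6739 to 95500. The homeobox gene HOXA10 (chromosome 7, 27170605 to 27180261) averaged 150.3 ± 5.30 CPM in vehicle and 0 counts in resistant 1, at least 2653-fold lower. MTAP, which encodes a methionine salvage enzyme (chromosome 9, 21802636 to 21937651), averaged 138 ± 3.61 CPM in vehicle and was at least 2438-fold lower. The homeobox gene IRX3 was at least 3973-fold lower, PHACTR3 at least 3472-fold, the adhesion gene PARVG at least 2762-fold, PID1 at least 2066-fold, the myelin basic protein gene MBP at least 1888-fold and FAM135B at least 1345-fold. BASP1 averaged 439 ± 12.3 CPM in vehicle against 1 count in resistant 1, a ratio of 23198 with an interval of 4163 to 916295.

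MTAP lies in a block of chromosome 9 from HACD4 (20999509 to 21031640) through KLHL9 and CDKN2A to CDKN2B (22002903 to 22009305), chosen after its values were seen. Only genes between FOCAD and CAAP1 that averaged at least 1 CPM in OCI-AML3 parental libraries were kept. These 5 genes had 0 counts in the 9 libraries labelled resistant, 46853 in the 6 vehicle libraries, 10031 in the 3 OCI-AML3 parental libraries and 1 in the 3 K562 libraries. HACD4, KLHL9 and MTAP are also among the genes above seen in OCI-AML3 but not in K562, so the block is not separate evidence.

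Sterol genes moved in both directions in batch 1. Of 20 cholesterol biosynthesis genes called both here and in K562 against OCI-AML3 parental, 19 had the same sign. The values below may therefore be a difference between cell lines, and they cannot tell it from resistance. HMGCS1, an early enzyme of sterol synthesis (chromosome 5, 43287470 to 43313512), rose from 128 ± 2.86 to 313 ± 11.9 CPM, a log2 fold change of 1.29 (SE 0.05, adjusted p = 3.3033e-19). SQLE, which oxidises squalene (chromosome 8, 124998497 to 125022283), rose by 1.16 (SE 0.05, adjusted p = 5.3253e-18). EBP rose by 2.12 and DHCR7, a late enzyme of the pathway, by 1.98, while PMVK fell by 1.65 on the log2 scale. The lysosomal cholesterol transporter gene NPC1 rose by 0.60 and INSIG1 by 0.29. The sterol regulator SREBF2 fell by 0.69 (SE 0.05, adjusted p = 2.6419e-13). SOAT1, which esterifies cholesterol, was lower (-0.15, adjusted p = 0.0262816), and its call ended without resistant 1 replicate 2 (-0.13) or vehicle replicate 1 (-0.15). ABCA1, a cholesterol exporter, averaged 13.2 ± 1.67 CPM in vehicle against 2 counts in resistant 1, a ratio of 354 with an interval of 97.6 to 2927. ABCG1 was not tested in batch 1.

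Most of the fixed inflammatory genes fell. Of 32 NF-kB targets called both here and in K562 against OCI-AML3 parental, 32 had the same sign, so the same limit holds here. IL1B (chromosome 2, 112829751 to 112836816) went from 65.4 ± 3.19 CPM in vehicle to 0.105 ± 0.127 CPM in resistant 1, a log2 fold change of -9.08 (SE 0.18, adjusted p = 1.1110e-25). The chemokine gene CXCL8 went from 239.7 ± 22.7 to 1.42 ± 0.177 CPM (-7.38, SE 0.10, adjusted p = 5.2971e-29). TNF averaged 136 ± 4.38 CPM in vehicle against 1 count, a ratio of 7207 with an interval of 1293 to 284711. The NF-kB subunit gene RELB changed by -4.34 (SE 0.18), and the NF-kB inhibitor genes TNFAIP3 by -1.97 (SE 0.07) and NFKBIA by -1.41 (SE 0.08). The interferon-stimulated gene MX1 had 3 counts in resistant 1, a ratio of 58.4 with an interval of 19.7 to 286. ISG15 rose by 1.55 (SE 0.18, adjusted p = 1.0714e-08), and IFIT1 was not called (0.11, adjusted p = 0.784604).

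Of the 37 lists tested in batch 1, 13 were called. Erythroid markers were higher (adjusted p = 9.5259e-10) with 29 of 30 members up and 1 down, and they stayed called at adjusted p = 0.00768148 with an estimated correlation. Monocyte and macrophage markers were lower (1.0002e-08) with 27 of 29 down, at adjusted p = 0.00768148 with an estimated correlation. The interferon gamma and antigen presentation list had 21 of 26 down, and neutrophil granule proteins had 13 of 15 down. Both had an adjusted p of 2.0611e-04, and of 0.0425788 with an estimated correlation. The 9 other calls were not held with an estimated correlation, whose adjusted p follows each. The inflammasome list was lower (3.4030e-04, then 0.249713) with 19 of 23 down, as were cytokines, chemokines and their receptors (8.5172e-04, then 0.0629175) with 31 of 44 down, NF-kB targets (0.0225724, then 0.182208) with 24 of 36 down and type I interferon genes (0.0413968, then 0.249713) with 24 of 40 down. Cholesterol biosynthesis was higher (0.0107617, then 0.0900998), with 17 of 22 up, 3 down and a median log2 fold change of 0.64. Histones were higher (0.0196912, then 0.122814) with 11 of 13 up. NRF2 targets (0.0458163, then 0.453463) had 18 of 24 up, oxidative phosphorylation (0.0458163, then 0.681899) 22 of 28 up, and ribosomal proteins (0.0458163, then 0.737937) 23 of 36 down. Counts of members adjusted over the list alone were the same for these 13 lists.

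Those last 3 calls also ended with 1 library left out. NRF2 targets had 0.0523688 without vehicle replicate 2. Oxidative phosphorylation had 0.0570376 without parental replicate 1, 0.0615797 without resistant 1 replicate 2, and 0.0606879 and 0.0523688 without vehicle replicates 1 and 2. Ribosomal proteins had 0.0679242 and 0.0878245 without resistant 1 replicates 1 and 3 and 0.0523688 without vehicle replicate 2.

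Members of the tested lists with large changes included, among those that rose, the lipid carrier gene APOE (10.92, SE 0.17), the signal transducer STAT5A (7.58, SE 0.08), the kinase gene PIM1 (6.30, SE 0.07) and IFITM3 (3.84, SE 0.08). The survival gene BCL2L1 rose by 2.73 (SE 0.07), while its relative BCL2 changed by -6.24 (SE 0.09). NLRP3, the sensor of an inflammasome, changed by -10.91 (SE 0.14). The lysosomal lipase gene LIPA, which frees cholesterol from esters, changed by -9.55 (SE 0.16), the carbonic anhydrase gene CA2 by -7.61 (SE 0.09), RPL30 by -1.10 (SE 0.05) and NDUFA4 by 1.06 (SE 0.06).

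The other 24 lists were not called in this comparison. Their adjusted p was 0.113809 for heat shock, 0.203998 for heparan and chondroitin sulfate synthesis, 0.245701 for G2 and M phase and for Toll-like receptors, 0.246737 for p53 targets, 0.306344 for progenitor markers, 0.32547 for sphingolipid metabolism, 0.337852 for flippases, and 0.3695 for JAK-STAT regulators and for the unfolded protein response. It was 0.422139 for cholesterol efflux, 0.431486 for fibroblast and epithelial markers, 0.448563 for membrane repair and for apoptosis, 0.604438 for S phase, 0.615739 for megakaryocyte and for lymphocyte markers, and 0.691984 for ABC transporters and for fatty acid synthesis. It was 0.71954 for hypoxia, 0.735996 for sialic acid synthesis and for lysosome genes, 0.748743 for immediate early genes and 0.998144 for sterol sensing. In the sterol sensing, sialic acid, hypoxia and immediate early lists the test, the median and the mean differed in sign.

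Resistant 1 against vehicle in batch 2 asks the same question in libraries sequenced separately. Erythroid and monocyte lists were again called, and both calls were lost with an estimated correlation (adjusted p = 0.241852 and 0.21409). Cholesterol biosynthesis was not called (0.939024). Of 15218 genes tested, 6079 rose and 5442 fell. HBG2 averaged 399 ± 63.6 CPM (SD, n = 3) in resistant 1 and 0 counts in vehicle, at least 15498-fold higher. RHAG was at least 12556-fold higher (324 ± 22.9 CPM), NCKAP1 at least 12479-fold, NMU at least 7810-fold, HEMGN at least 6099-fold, CAVIN2 at least 5882-fold, DCAF4L2 at least 5511-fold, UCA1 at least 4274-fold, OR51B5 at least 4239-fold and MAGEA3 at least 2930.2-fold. IRF8 averaged 1205 ± 75.4 CPM in vehicle and was at least 48847-fold lower, BASP1 at least 10933-fold, PID1 at least 9769-fold, MTAP at least 8338-fold, HOXA10 at least 8193-fold, PHACTR3 at least 6523-fold, IRX3 at least 6520.2-fold, MBP at least 5279-fold and FAM135B at least 4467-fold. PARVG had 1 count in resistant 1, a ratio of 16565 with an interval of 2973 to 654340. HEMGN had the greatest adjusted p of these 20, 9.1776e-09.

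Among sterol genes of batch 2, HMGCS1 (0.30, adjusted p = 0.09934), SQLE (0.02, adjusted p = 0.930395) and INSIG1 (-0.14, adjusted p = 0.636979) were not called. HMGCS1 was called with only the groups compared in the fit (0.31) and without resistant 2 replicate 2 (0.30) or 3 (0.30). EBP rose by 2.11 (SE 0.12, adjusted p = 8.7865e-10). SREBF2 changed by -0.71 (SE 0.10), SOAT1 by -0.76 (SE 0.12) and NPC1 by 0.53 (SE 0.11). ABCA1 changed by -8.45 (SE 0.48), and ABCG1 had 1 count in resistant 1, a ratio of 148 with an interval of 26.2 to 5899. IL1B changed by -7.88 (SE 0.29, adjusted p = 5.0059e-12), CXCL8 by -6.60 (SE 0.65), RELB by -2.43 (SE 0.39), NFKBIA by -0.67 (SE 0.14), MX1 by -5.21 (SE 0.66) and ISG15 by 1.43 (SE 0.27). TNF had 1 count in resistant 1, a ratio of 2919 with an interval of 524 to 115348. TNFAIP3 (0.03, adjusted p = 0.927137) and IFIT1 (0.03, adjusted p = 0.961015) were not called.

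In batch 2, 8 lists were called for resistant 1, and 0 of them were held with an estimated correlation. Each has that adjusted p after it. Erythroid markers were higher (1.1523e-10, then 0.241852) with 29 of 30 up, and histones were higher (0.0221064, then 0.511645) with 10 of 13 up. Monocyte markers (5.5873e-07, then 0.21409) had 24 of 27 down and neutrophil granule proteins (0.00167882, then 0.21409) 12 of 15 down. The inflammasome list (0.00531422, then 0.511645) had 17 of 24 down, or 18 when adjusted over the list alone. Interferon gamma (0.0273781, then 0.511645) had 16 of 26 down and was not called without the low-count filter (0.0518497). Cytokines (0.0273781, then 0.566085) had 27 of 44 down. Ribosomal proteins (0.0330496, then 0.963942) had 22 of 36 down, or 21 when adjusted over the list alone, and were not called without resistant 1 replicate 2 (0.149222) or vehicle replicate 1 (0.0913658) or 3 (0.0588876). Cholesterol biosynthesis (0.939024, 8 up and 4 down), NF-kB targets (0.828307, 16 up and 17 down) and type I interferon genes (0.407391, 17 up and 19 down) were not called.

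Resistant 2 against vehicle in batch 2 asks whether a second resistant biological replicate differed from vehicle in a similar way. As lists, erythroid markers were called higher and monocyte markers and ribosomal proteins lower, and these calls were lost with an estimated correlation (adjusted p = 0.232644, 0.196259 and 0.860589). Of 15218 genes tested, 6124 rose and 5462 fell. RHAG averaged 297 ± 54.2 CPM (SD, n = 3), at least 11541-fold higher, NCKAP1 was at least 10146-fold higher, DCAF4L2 at least 10080.4-fold, HBG2 at least 8877-fold, HEMGN at least 6497-fold (167 ± 68.1 CPM), CAVIN2 at least 5532-fold, OR51B5 at least 4885-fold, NMU at least 3391-fold, MAGEA3 at least 3388-fold and UCA1 at least 3266-fold. IRF8 was at least 55777-fold lower, PID1 at least 11155-fold, MTAP at least 9521-fold, HOXA10 at least 9355-fold, PHACTR3 at least 7449-fold, MBP at least 6028-fold and FAM135B at least 5101-fold. BASP1 had 1 count (ratio 37733, interval 6772 to 1490416), PARVG 1 count (18915, 3394 to 747163) and IRX3 2 counts (11163, 3090 to 92185).

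Most fixed sterol genes of resistant 2 were lower or not called. INSIG1 changed by -1.004 (SE 0.25, adjusted p = 0.00331634), SREBF2 by -0.95 (SE 0.10), SOAT1 by -0.92 (SE 0.12), ABCA1 by -6.28 (SE 0.39), ABCG1 by -4.70 (SE 0.62) and the demethylase gene CYP51A1 by -1.56 (SE 0.16, adjusted p = 3.6078e-07). NPC1 (0.73, SE 0.11) and EBP (1.98, SE 0.12) rose. HMGCS1 (-0.08, adjusted p = 0.651722) and SQLE (-0.02, adjusted p = 0.909684) were not called, and both were called lower without resistant 2 replicate 2 (-0.31 and -0.30). IL1B changed by -8.62 (SE 0.31, adjusted p = 3.0875e-12), TNF by -8.98 (SE 0.45), CXCL8 by -4.63 (SE 0.58), RELB by -1.49 (SE 0.36), NFKBIA by -1.25 (SE 0.14) and MX1 by -3.12 (SE 0.53). TNFAIP3 (1.10, SE 0.31), IFIT1 (1.47, SE 0.44) and ISG15 (2.65, SE 0.27) rose, as did the apoptosis inhibitor gene BIRC3 (6.15, SE 0.40) and the stress gene GADD45A (4.94, SE 0.16).

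The list tests of resistant 2 made 8 calls, of which 0 were held with an estimated correlation (given after each). Erythroid markers (1.2395e-09, then 0.232644) had 28 of 30 up, histones (0.00590555, then 0.481846) 11 of 13 up, and fibroblast and epithelial markers (0.022697, then 0.232644) 9 of 12 up. The last was not called without the low-count filter (0.106104). Monocyte markers (2.9274e-07, then 0.196259) had 24 of 27 down, neutrophil granule proteins (6.4871e-04, then 0.184655) 13 of 15 down, ribosomal proteins (8.9264e-04, then 0.860589) 29 of 36 down, the inflammasome list (0.00654064, then 0.535225) 15 of 24 down and cytokines (0.00944595, then 0.539332) 28 of 44 down. Counts of members adjusted over the list alone were the same for these 8 lists. Cholesterol biosynthesis (0.696349, 7 up and 9 down), NF-kB targets (0.720038, 16 up and 18 down) and type I interferon genes (0.496428, 15 up and 21 down) were not called.

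**Figure D2:**
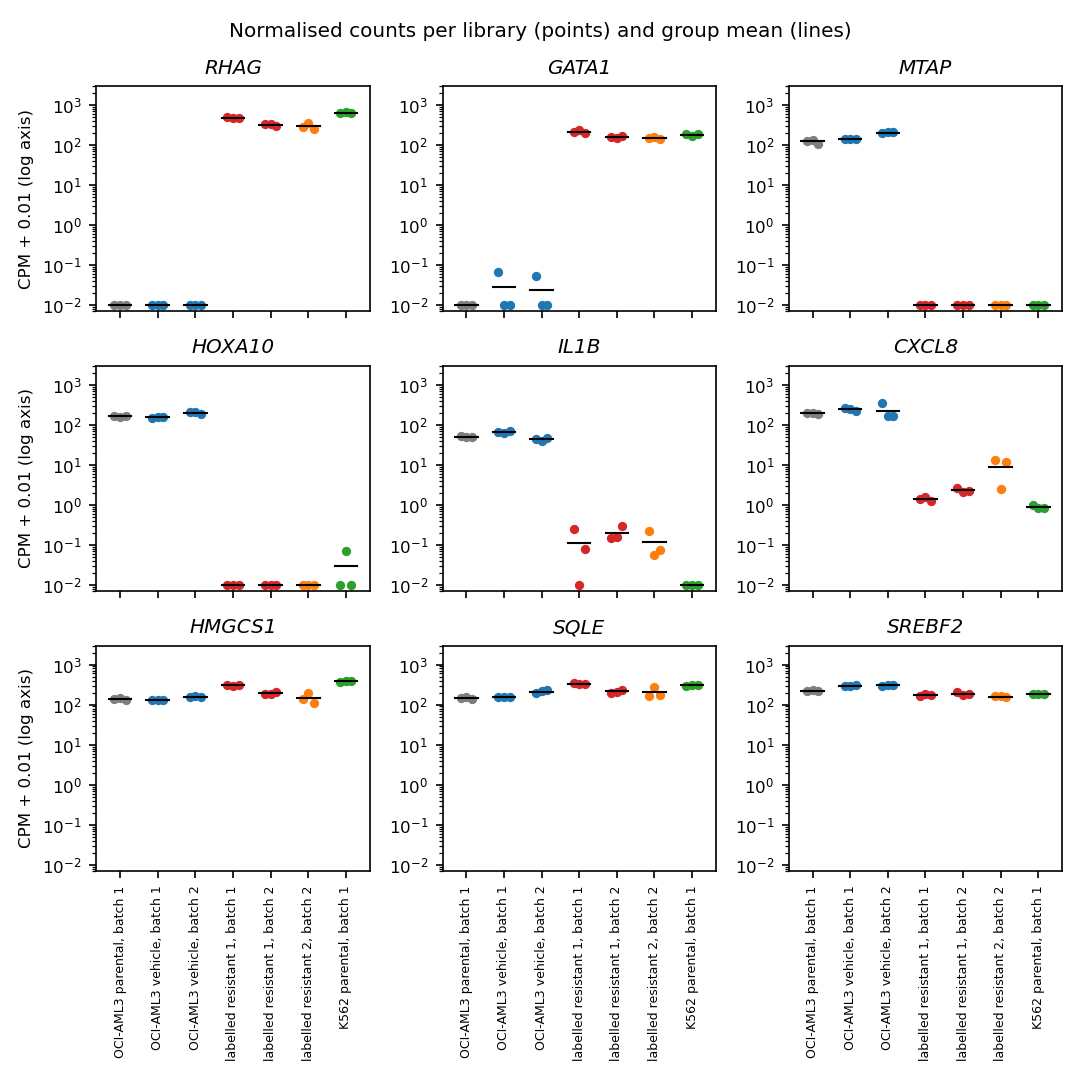
CPM plus 0.01 on a log axis for RHAG, GATA1, MTAP, HOXA10, IL1B, CXCL8, HMGCS1, SQLE and SREBF2, with 1 point per library and a line at each group's mean. MTAP and HOXA10 are at 0 counts and RHAG at 297 to 483 CPM on average in the 3 groups labelled resistant.

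Over both batches with batch as a term, 6567 genes rose and 5784 fell in resistant 1 among 15209 tested. HMGCS1 rose by 0.82 (SE 0.15, adjusted p = 1.3164e-04) and SQLE by 0.62 (SE 0.17, adjusted p = 0.00391475), and NPC1 by 0.60 (SE 0.07), while INSIG1 (0.11, adjusted p = 0.289556) was not called. The batches differed for HMGCS1 (1.29 in batch 1 and 0.30 in batch 2) and SQLE (1.16 and 0.02), and neither was called in batch 2. IL1B changed by -8.24 (SE 0.22, adjusted p = 9.5169e-14) and RELB by -3.17 (SE 0.31). Lists called were erythroid (1.5005e-09) and histones (0.0187737), both higher, and monocyte (1.4778e-07), neutrophil (3.3890e-04), inflammasome (7.7316e-04), interferon gamma (0.00441054) and cytokine genes (0.00494015), all lower. With an estimated correlation the adjusted p was 0.607302 for interferon gamma and cytokine genes and 0.38113 for the others. Cholesterol biosynthesis was not called (0.242416, 13 up and 4 down).

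In all 3 comparisons with vehicle, 4400 genes were called higher and 4232 lower among 14179 tested in each, against 917.9 and 838 if the lists were independent. Another 251 genes were called in all 3 with differing signs. Resistant 1 enters the comparisons of both batches, so the 3 are not independent biological replicates. Resistant 1 and resistant 2 of batch 2 shared 3 vehicle libraries, which by itself gave simulated unchanged groups a mean correlation of fold changes of 0.520 in 10 simulations, against an observed correlation of 0.976. These resistant groups of batch 2 had 5396 genes called up and 4735 called down in common, against 0 of each in every simulation. Unchanged groups are bound to give few calls, so the simulated 0 does not show how far shared libraries raise the overlap of changed groups. Because of the shared libraries, the counts for independent lists are not those of unchanged groups. The covariance of fold changes was 14.9, against a simulated 0.0673.

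The interaction of resistant 1 with batch asks whether its difference from vehicle was of equal size in both batches. As lists, cholesterol biosynthesis was called lower in the batch 2 effect and the unfolded protein response and NF-kB targets higher, and these calls were lost with an estimated correlation (adjusted p = 0.338339 for the first and 0.101995 for the others). Of 15209 genes tested, 2281 were higher and 2773 lower in the batch 2 effect. Which direction had more genes depended on the scaling, with 2614 higher and 2307 lower under RLE normalization and 2709 and 2440 with DESeq2. SQLE changed by -1.16 (SE 0.11, adjusted p = 5.7830e-07), HMGCS1 by -1.02 (SE 0.10, adjusted p = 9.2271e-07) and DHCR7 by -1.24 (SE 0.18). TNFAIP3 changed by 1.99 (SE 0.19, adjusted p = 1.0742e-06), RELB by 1.90 (SE 0.37, adjusted p = 7.3164e-04) and NFKBIA by 0.72 (SE 0.16). The serine synthesis gene PHGDH (2.02, SE 0.14), the cell cycle inhibitor gene CDKN1A (2.29, SE 0.23) and LYZ (1.76, SE 0.11) were higher, and the chaperone gene HSPA8 (-1.77, SE 0.15) and the hexokinase gene HK2 (-1.44, SE 0.13) lower. IL1B (adjusted p = 0.154705) and CXCL8 (adjusted p = 0.360233) were not called with all libraries. CXCL8 was called higher without vehicle of batch 2 replicate 1 (1.218), and IL1B without resistant 1 of batch 1 replicate 1, where few counts were left. Of the lists, 14 were called, of which 0 were held with an estimated correlation. The lowest adjusted p was 2.0907e-07 for the unfolded protein response, higher with 18 of 28 members up (adjusted p = 0.101995 with an estimated correlation). NF-kB targets were higher (1.6169e-06) with 22 up and 2 down of 37, or 23 and 4 when adjusted over the list alone (adjusted p = 0.101995 with an estimated correlation). Cholesterol biosynthesis was lower (1.7275e-04) with 13 of 22 down and 1 up (adjusted p = 0.338339 with an estimated correlation).

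Resistant 2 against resistant 1 in batch 2 compares the resistant biological replicates directly. They differed in fewer genes than either did from vehicle. As lists, erythroid (13 of 30 members down), lysosomal (12 of 30) and oxidative phosphorylation genes (9 of 28) were called lower in resistant 2, and immediate early genes (7 of 21 up) and histones (7 of 13) higher. These calls were lost with an estimated correlation (adjusted p = 0.593342 for oxidative phosphorylation and 0.545649 for the others). Of 15218 genes tested, 1890 rose and 1816 fell, in all 3706. Leaving out 1 library gave 2323 to 4814 genes, with 2467 without resistant 1 replicate 1, 2323 without resistant 1 replicate 3, 2387 without resistant 2 replicate 1 and 2431 without resistant 2 replicate 3, and in these 4 more genes fell than rose. The collagen gene COL1A2 (chromosome 7, 94394895 to 94431227) rose by 4.19 (SE 0.44, adjusted p = 3.0643e-05), from 0.989 ± 0.753 to 18.4 ± 6.78 CPM (SD, n = 3). CYTIP rose by 3.40 (SE 0.33), GCA by 3.10 (SE 0.17), MAGEB16 by 3.08 (SE 0.26), SYTL5 by 3.07 (SE 0.22) and the interferon-induced GTPase gene GBP4 by 2.91 (SE 0.23). RASGRP3 rose by 3.06 (adjusted p = 0.0123796) and was not called without the low-count filter (3.06) or without resistant 2 replicate 3 (2.85). The multidrug transporter gene ABCB1 (chromosome 7, 87503017 to 87713323) rose by 2.98 (SE 0.17, adjusted p = 8.1985e-08), from 6.15 ± 1.25 to 48.9 ± 3.91 CPM. The folate enzyme gene ALDH1L1 (chromosome 3, 126103562 to 126197994) changed by -5.63 (SE 0.28, adjusted p = 2.0522e-08) and the coagulation factor gene F8 by -4.42 (SE 0.20). SLC6A19 (-4.12, SE 0.17), B4GALT6 (-4.07, SE 0.31), LPCAT2 (-3.49, SE 0.14), the cytokine receptor gene CSF2RB (-3.48, SE 0.23) and CATSPERB (-3.42, SE 0.35) were also lower. The lysosomal membrane gene LAPTM5 went from 607 ± 48.4 to 47.5 ± 9.14 CPM (-3.68, SE 0.15, adjusted p = 3.0507e-09). In batch 1, COL1A2 (-2.60, SE 0.10) and ABCB1 were also lower in resistant 1 than in K562 parental libraries. The rise of these genes may thus stem from a low level in resistant 1 rather than a gain in resistant 2, which was not tested.

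Among list members, the death receptor gene FAS rose in resistant 2 by 3.07 (SE 0.22, adjusted p = 5.1467e-07), the RNA sensor gene IFIH1 by 2.08 (SE 0.16) and GBP3 by 3.03 (SE 0.35), and the haemoglobin chaperone gene AHSP changed by -1.77 (SE 0.30, adjusted p = 0.00134656), GYPB by -1.42 (SE 0.29), the protease gene CTSD by -1.55 (SE 0.13) and NPC2 by -1.60 (SE 0.19). The 8 lists called were not held with an estimated correlation, given after each. They were erythroid (2.8686e-04, then 0.545649; 0 up, 13 down), oxidative phosphorylation (0.00116152, then 0.593342; 0 up, 9 down), lysosome (0.00204382, then 0.545649; 1 up, 12 down, or 2 and 13 when adjusted over the list alone) and ribosomal genes (0.00204382, then 0.722323; 0 up, 7 down), G2 and M phase (0.00559281, then 0.722323), immediate early genes (0.0174568, then 0.545649), histones (0.0297507, then 0.545649) and NRF2 targets (0.0319676, then 0.545649). G2 and M phase had 4 down, and was not called without resistant 2 replicate 1 (0.0665373) or 3 (0.125408). Immediate early genes and histones each had 7 up, and histones were not called without resistant 2 replicate 1 (0.0665373). NRF2 targets had 5 down and were not called without resistant 2 replicate 3 (0.0608704). Cholesterol biosynthesis had 8 down and 0 up and was not called (0.057544). It was called without the low-count filter (0.0294802), with the sample number as a block (0.0404646), without resistant 1 replicate 1 (0.00797586) and without resistant 2 replicate 2 (0.00235008), and had an adjusted p of 0.722323 with an estimated correlation.

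Vehicle against parental OCI-AML3 in batch 1 gives the background of the vehicle control. As lists, heat shock, G2 and M phase, S phase and p53 genes were called lower in vehicle, and these calls were lost with an estimated correlation (adjusted p = 0.124267, 0.21322, 0.168877 and 0.0513044). Most changes were small. Of 14505 genes tested, 2715 rose and 2658 fell, and 678 changed by an absolute log2 fold change of 1 or more. The secreted hormone gene STC2 (chromosome 5, 173314723 to 173328447) rose from 0.767 ± 0.187 to 51.3 ± 2.45 CPM (SD, n = 3; 6.05, SE 0.13, adjusted p = 1.2862e-22). The complement gene C3 (chromosome 19, 6677704 to 6730562) rose by 5.72 (SE 0.13), the cytokine gene IL32 by 4.68 (SE 0.13), the protease gene MMP9 by 4.15 (SE 0.07), CHAC1, an integrated stress response gene, by 4.04 (SE 0.12), DDIT4 by 3.68 (SE 0.10), AKR1C3 by 3.66 (SE 0.14) and THBS1 by 3.42 (SE 0.11). The growth factor gene TGFA changed by -2.79 (SE 0.15, adjusted p = 4.2358e-13), FOSB by -2.68 (SE 0.18), DLX3 by -2.61 (SE 0.09), the neurotrophin receptor gene NGFR by -2.44 (SE 0.15), the neuropeptide gene NPY by -2.20 (SE 0.12), MYO1A by -1.98 (SE 0.15), C3ORF52 by -1.93 (SE 0.14) and FAT1 by -1.74 (SE 0.14).

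Fixed genes in vehicle against parental changed little in sterol synthesis and rose among NF-kB targets. TNFAIP3 rose by 2.18 (SE 0.07, adjusted p = 1.0829e-18), ABCA1 by 1.219 (SE 0.13), RELB by 0.54 (SE 0.11), INSIG1 by 0.47 (SE 0.05), NFKBIA by 0.41 (SE 0.07), SREBF2 by 0.40 (SE 0.05), IL1B by 0.36 (SE 0.07) and CXCL8 by 0.29 (SE 0.06). MX1 (-1.34, SE 0.16) and IFIT1 (-1.90, SE 0.28) were lower. SQLE (adjusted p = 0.197583), NPC1 (adjusted p = 0.809561), SOAT1 (adjusted p = 0.552961), TNF (adjusted p = 0.835508) and ISG15 (adjusted p = 0.0745032) were not called. ISG15 was called lower without parental replicate 2 (-0.61) or vehicle replicate 2 (-0.76). HMGCS1 was lower by a log2 fold change of -0.13 (adjusted p = 0.0433828), and was not called under the other normalization, filter, tests or sets of libraries tried (-0.14 to -0.10), except without parental replicate 3.

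Of the lists, 11 were called in vehicle against parental and 0 were held with an estimated correlation, given after each. Lower in vehicle were heat shock (3.1149e-06, then 0.124267; 11 of 17 down, 12 when adjusted over the list alone), G2 and M phase (2.0618e-05, then 0.21322; 14 of 28, then 16), p53 targets (6.4877e-05, then 0.0513044; 16 of 25, then 16), S phase (1.1444e-04, then 0.168877; 16 of 28) and type I interferon genes (0.00368116, then 0.168877; 18 of 40, then 24). Higher were monocyte markers (1.1444e-04, then 0.0513044) with 16 of 29 up, NF-kB targets (5.5398e-04, then 0.124267) with 18 of 36 up, hypoxia (0.00520247, then 0.268624) with 14 of 30 up, cytokines (0.0182045, then 0.168877) with 20 of 44 up, cholesterol efflux (0.0230873, then 0.259618) with 8 of 17 up, and ribosomal proteins (0.00955598, then 0.666742) with 14 of 36 up. The last was not called without parental replicate 2 (0.117749). Adjusted over the list alone, 17 monocyte and 19 NF-kB genes were up, and the numbers up of the other 4 lists were the same. VEGFA rose by 1.86 (SE 0.07) and FCN1 by 3.20 (SE 0.16), while TYMS changed by -0.64 (SE 0.04) and OAS1 by -1.58 (SE 0.22). Cholesterol biosynthesis was not called (0.987714), with 4 up and 6 down, a median of -0.03 and a mean of 0.03.

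K562 against OCI-AML3 parental compares the untreated lines. As lists, erythroid and cholesterol biosynthesis genes were called higher in K562 and monocyte and neutrophil genes lower, and these calls were lost with an estimated correlation (adjusted p = 0.0538744, 0.135061, 0.150624 and 0.138117). Of 13883 genes tested, 5915 were higher and 5905 lower in K562, a near balance that was 5836 and 5965 under RLE normalization. RHAG averaged 636 ± 19.6 CPM (SD, n = 3) in K562, at least 10005.9-fold higher (adjusted p = 4.2403e-24). The globin genes HBG1 (at least 6487-fold), HBZ (at least 4035.5-fold) and HBE1 (1060 ± 15.7 CPM against 1 count, ratio 50053, interval 8983 to 1977016) were higher, with GALNT5 (at least 5281-fold), HEMGN (at least 4952-fold), CTCFL (at least 4380.3-fold) and NCKAP1 (at least 4139.8-fold). Lower in K562 were CES1 (at least 5160.4-fold), IRX3 (at least 4072-fold), PHACTR3 (at least 3080.5-fold), PTPRN2 (at least 2344-fold), TNF (at least 2284-fold), MTAP (at least 2041-fold), the neutrophil protease gene CTSG (3 counts, ratio 20332, interval 6957 to 98593) and NAV3 (1 count, ratio 22814, interval 4094 to 901133).

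Sterol genes in K562 were higher for INSIG1 (1.57, SE 0.05, adjusted p = 1.6843e-17), HMGCS1 (1.45, SE 0.05), SQLE (1.06, SE 0.05), NPC1 (0.98, SE 0.07) and DHCR7 (2.69, SE 0.06), and SREBF2 was lower (-0.25, SE 0.05). Inflammatory genes in K562 were lower for CXCL8 (-7.81, SE 0.10), RELB (-4.52, SE 0.22), IFIT1 (-4.25, SE 0.39), NFKBIA (-1.28, SE 0.09), IL1B (at least 844-fold) and MX1 (at least 139-fold). ABCA1 had 1 count in K562, a ratio of 284 with an interval of 50.6 to 11274. SOAT1 (adjusted p = 0.281278) was not called. TNFAIP3 (-0.18, adjusted p = 0.0936983) was called with all 4 groups of batch 1 in the fit (-0.18) and without OCI-AML3 parental replicate 3 (-0.25). ISG15 rose by 0.50 (adjusted p = 0.0085015) and was not called without OCI-AML3 parental replicate 2 (0.36).

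The lists called for K562 numbered 11, of which 0 were held with an estimated correlation. Higher were erythroid (2.9556e-10, then 0.0538744) with 30 of 31 up, cholesterol biosynthesis (3.3876e-04, then 0.135061) with 20 of 22 up, histones (0.00720248, then 0.150624) with 11 up and NRF2 targets (0.0286238, then 0.383026) with 18 up. Lower were monocyte (1.9117e-08, then 0.150624) with 25 down, neutrophil (2.6841e-04, then 0.138117) with 13 down, inflammasome (3.0962e-04, then 0.135061) with 18 down, cytokine (8.9493e-04, then 0.138117) with 29 down, type I interferon (8.9493e-04, then 0.150624) with 31 down and interferon gamma (8.9493e-04, then 0.179271) with 20 down, and p53 targets (0.0286238, then 0.227219) with 17 down. Adjusted over the list alone, the counts of these 11 lists were the same. NF-kB targets (0.0600906, 10 up and 22 down) were not called, and were called without the low-count filter (0.0172028).

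The fold changes of the libraries labelled resistant against vehicle were then set beside those of K562 against OCI-AML3 parental. The contrasts have no library in common. Across 13812 genes, the log2 fold changes of resistant 1 in batch 1 had a Pearson r of 0.970 and a Spearman rho of 0.945 with those of K562, with a slope of 0.943. Of 10809 genes called in both, 10514 (97.3%) had the same sign, of which 5295 were up and 5219 down, against 2562 and 2505 for independent lists. In batch 2, across 13650 genes, r was 0.942 for resistant 1 and 0.935 for resistant 2, and 92.3% of 9238 and 91.5% of 9235 genes called in both had the same sign. Genes are not independent replicates. By list, 19 of 20 cholesterol biosynthesis genes, 32 of 32 NF-kB targets and 30 of 30 erythroid genes called in both contrasts had the same sign in resistant 1 of batch 1 and in K562, as did 17 of 23 genes of the unfolded protein response. For cholesterol biosynthesis the numbers were lower in batch 2, with 10 of 12 in resistant 1 and 9 of 16 in resistant 2.

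**Figure D3:**
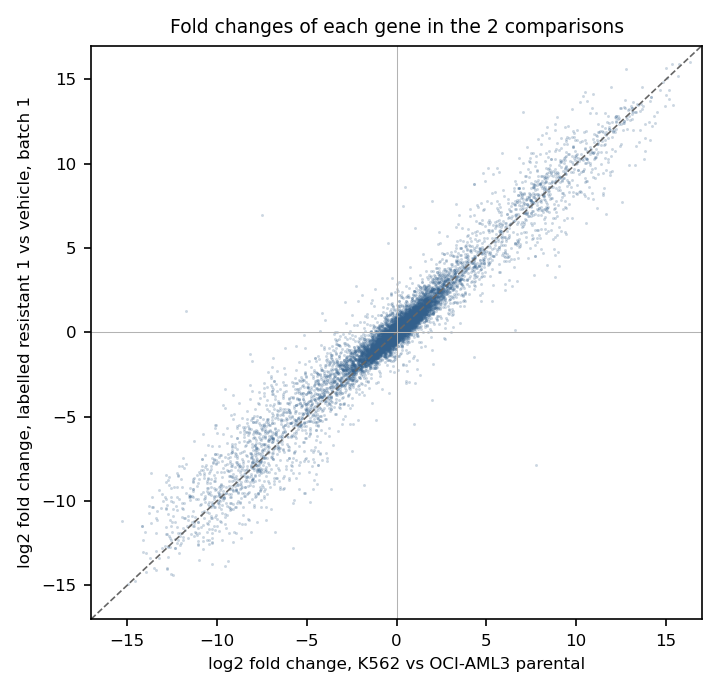
Log2 fold change of each gene in resistant 1 against vehicle of batch 1 (vertical) and in K562 against OCI-AML3 parental (horizontal), 1 point per gene, with a dashed line where both are equal. Pearson r across 13812 genes is 0.970 with a slope of 0.943.

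**Figure D4:**
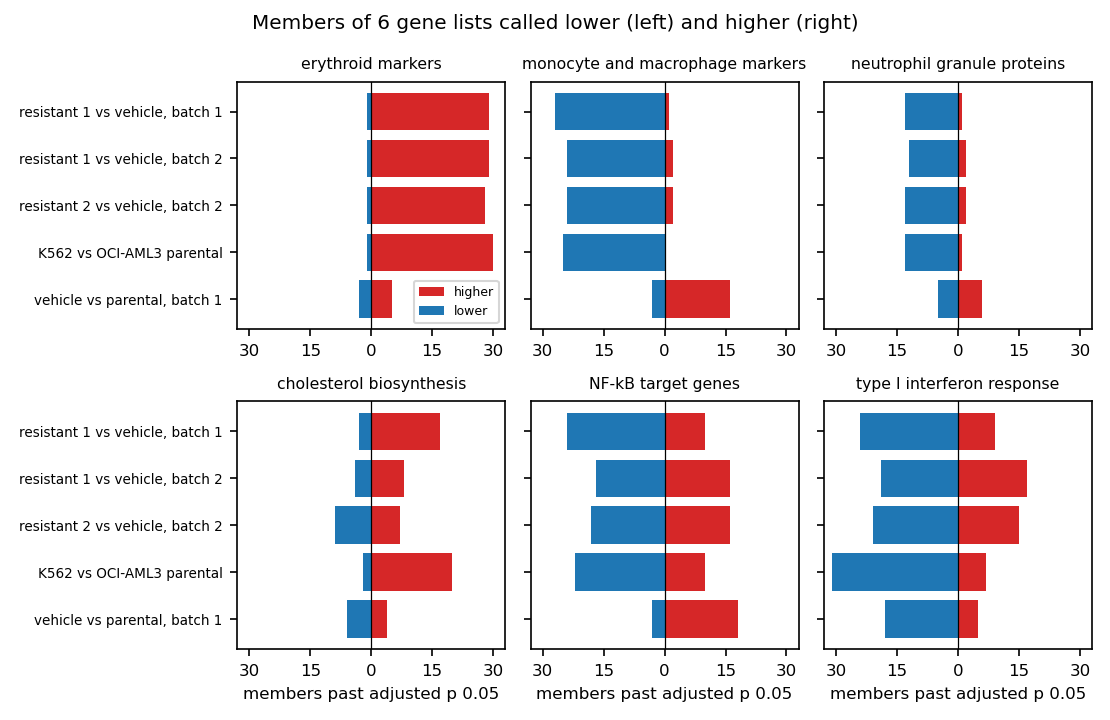
Number of members called higher or lower for 6 gene lists in 5 comparisons. In resistant 1 of batch 1 erythroid markers have 29 members up and 1 down and cholesterol biosynthesis 17 up and 3 down.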

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

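Tests chosen after the results were seen were the splits of the libraries, the removal of trends on GC content and transcript length, and the thinning of batch 2. Leaving out each library was planned, and its use as a test of an atypical library was chosen afterwards.

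The difference of resistant 1 from vehicle was not of equal size in the batches, by the test of the interaction itself, for 5054 genes. Lower in the batch 2 effect were SQLE, HMGCS1, INSIG1 and the esterification gene SOAT1, with log2 differences of -1.16, -1.02, -0.45 and -0.63, while SREBF2 (-0.03, adjusted p = 0.891736), NPC1 (-0.09, adjusted p = 0.648349), ABCA1 (-0.15, adjusted p = 0.99993) and ABCG1 (-0.69, adjusted p = 0.857752) were not called. The NF-kB pathway genes differed, TNFAIP3 by 1.99, RELB by 1.90 and NFKBIA by 0.72, while TNF (1.59, adjusted p = 0.788555), IL1B (adjusted p = 0.154705) and CXCL8 (adjusted p = 0.360233) were not called with all libraries. CXCL8 was called without vehicle of batch 2 replicate 1 (1.218), and IL1B without resistant 1 of batch 1 replicate 1. Lists higher in the batch 2 effect were the unfolded protein response (adjusted p = 2.0907e-07), NF-kB targets (1.6169e-06), interferon gamma (9.2355e-06), monocyte markers (1.5820e-05), p53 targets (1.9545e-04), cytokines (0.00133822), G2 and M phase (0.00290126), type I interferon (0.00506627), inflammasome (0.0112692) and neutrophil granule proteins (0.014903). Lists lower in it were erythroid markers (1.5820e-05), cholesterol biosynthesis (1.7275e-04), heat shock (1.9545e-04) and hypoxia (0.0297205). With an estimated correlation the adjusted p was 0.101995 for the unfolded protein, NF-kB, interferon gamma, monocyte, p53, neutrophil and erythroid lists, 0.110286 for cytokines, 0.591608 for G2 and M phase and 0.338339 for the others, so 0 of the 14 were held. Adjusted over the list alone, the interferon gamma list had 19 members up in place of 17, p53 targets 13 in place of 12 and heat shock 13 down in place of 10. Neutrophil granule proteins were not called without the low-count filter (0.10107) or without resistant 1 of batch 1 replicate 1 (0.0733006), and hypoxia not without resistant 1 of batch 1 replicate 2 (0.0545422). Of 40 splits that exchanged libraries between the batches, within vehicle and within resistant 1, 1, the real one, gave as many called genes, and the highest other gave 1624. The other splits also put the general difference between the batches into the spread, which lowers their counts even without an interaction. They cannot decide whether the interaction arose by chance, and no conclusion is drawn from them.

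The batches of this interaction differ in depth, and a technical source was weighed first. After removal of each library's trend on GC content and transcript length, 4204 of the 5054 genes were still called, which argues against that trend as the whole cause, and after thinning batch 2 to a mean of 17.8 M counts 4458 were, which argues against depth as the whole cause. Between the batches, 9367 genes were called in vehicle libraries and 8862 in resistant 1 libraries, so a difference in culture or handling of either group may lie behind the interaction. It cannot be told apart from a change in the resistant cells, because batch and depth change together and the labels say neither how the batches were handled nor whether they share cultures. A biological change in the cells labelled resistant 1 between the batches stays open and was not tested.

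Resistant 2 differed from resistant 1 within batch 2, by a direct test, in 3706 genes. The count was 2467 or 2323 without resistant 1 replicate 1 or 3 and 2387 or 2431 without resistant 2 replicate 1 or 3. Lists lower in resistant 2 were erythroid markers (adjusted p = 2.8686e-04), oxidative phosphorylation (0.00116152), lysosome and ribosomal protein genes (0.00204382 each), G2 and M phase (0.00559281) and NRF2 targets (0.0319676). Immediate early genes (0.0174568) and histones (0.0297507) were higher. None of these 8 was held with an estimated correlation (adjusted p of 0.545649 to 0.722323). The 10 splits of these 6 libraries are too few for a share under 0.05, with 3706 called genes in the real split and 0 as the highest of the others.

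Fixed genes differed as well, with log2 fold changes of resistant 2 against resistant 1 of 2.17 for ABCA1, 1.97 for CXCL8, 1.44 for IFIT1, 1.2195 for ISG15, 1.06 for TNFAIP3, -0.58 for NFKBIA and -0.87 for INSIG1. Of these 7 calls, 5 ended when any 1 of 4 or 5 libraries was left out, with folds of similar size. ISG15 was called with each library left out. NFKBIA was not called without resistant 1 replicate 3 (-0.46). IFIT1 was not called without resistant 1 replicate 1 (1.30) or 2 (1.33) or resistant 2 replicate 1 (1.44) or 3 (1.38). INSIG1 was not called without resistant 1 replicates 1, 2 or 3 (-0.86, -0.84 and -0.92) or resistant 2 replicate 1 (-0.84). ABCA1 (1.88 to 2.37), CXCL8 (1.60 to 2.07) and TNFAIP3 (0.83 to 1.14) were not called without any 1 of resistant 1 replicates 1, 2 and 3 and resistant 2 replicates 1 and 3. ABCA1, CXCL8, TNFAIP3 and INSIG1 were not called without the low-count filter (2.17, 1.97, 1.07 and -0.87) either, and ABCA1 had 12 counts in resistant 1.

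A single atypical library was weighed against a difference between the resistant replicates. The lowest count with 1 library left out was 2323 genes, without resistant 1 replicate 3, which argues against 1 library as the whole source. Replicate 2 stood apart in each group of batch 2. The chi-square per gene of its pairs was 84.5 and 76.7 in resistant 2 (24.1 for the other pair) and 40.5 and 68.3 in resistant 1 (20.8 for the other pair). In vehicle it was 32.7 and 48.7 (20.8 for the other pair). The counts without replicate 2 of resistant 2, resistant 1 and vehicle were 4814, 3800 and 3548. With the sample number as a block the count was 4543, and an effect shared by sample number in batch 2 stays open. After removal of trends on GC content and transcript length, 3598 of the 3706 genes were still called, which argues against that trend. A difference between the resistant biological replicates themselves may remain, and it cannot be parted from separate culture histories, which were not tested. The values are those of 3 libraries per group in 1 batch.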

How the results depend on the processing

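The comparison of resistant 1 with K562 and the corrections for GC content, length and depth were tests chosen after seeing the data. Of 149 alternatives for the counts of called genes, 144 stayed within 1.5 times the count reported. Requiring an absolute log2 fold change of 1 or more left 4950 of the 8632 shared resistance genes, by construction. Leaving out 1 library gave 2323 to 4814 genes for resistant 2 against resistant 1. The counts that moved were 2467 without resistant 1 replicate 1, 2323 without resistant 1 replicate 3, 2387 without resistant 2 replicate 1 and 2431 without resistant 2 replicate 3, and the highest was without resistant 2 replicate 2. The cause was not tested.

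With each library left out in turn, resistant 1 against vehicle gave 12239 to 12790 genes in batch 1, 10998 to 12053 in batch 2 and 12170 to 12539 over both. Resistant 2 against vehicle gave 11187 to 11952, the interaction 4187 to 6003, vehicle against parental 4445 to 5530, K562 against OCI-AML3 11562 to 11931, resistant 1 against K562 6919 to 7634 and the shared genes 8259 to 8763. In batch 1, resistant 1 against vehicle gave 12474 genes with RLE, 14042 without the low-count filter, 12203 with DESeq2 and 12481 with only the groups compared. RLE shifted the log2 fold changes of a comparison by a median of 0.064 at most, in the interaction. There the median over genes went from -0.02 to 0.04 and the balance turned, from 2281 higher and 2773 lower to 2614 and 2307, or 2709 and 2440 with DESeq2. Vehicle against parental without the libraries labelled resistant gave 5184 genes. Leaving out all libraries labelled resistant leaves no comparison of resistance.

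With the sample number as a block, the counts were 12403 and 11858 genes for resistant 1 against vehicle in batches 1 and 2, 11939 for resistant 2 against vehicle and 4543 for resistant 2 against resistant 1. In that last comparison the block called MX1, RELB and HMGCS1 and the cholesterol (0.0404646) and fatty acid (0.0252956) lists, and no longer MSMO1. Over all comparisons it added 3 gene calls and 2 list calls and ended 9 gene calls, CXCL8 and NFKBIA in resistant 1 against K562 among them.

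Of 19579 gene values under alternatives, 19155 kept their direction and side of the threshold, 401 lost the call, 23 gained it and 0 reversed. Of 4651 list values, 4310 kept both, 106 lost the call, 229 gained it and 6 reversed. The 80 list calls of 296 became 4 with an estimated correlation, between 78 and 86 with 1 library left out, and 223 with fry, which asks whether a list's genes move 1 way on balance, without comparison to other genes. The 6 reversals were with fry. They were lymphocyte markers in resistant 1 of batch 1 (4.9825e-07), sterol sensing (5.3205e-05), fatty acid synthesis (0.00280673) and membrane repair (2.3731e-06) in resistant 1 of batch 2, membrane repair in resistant 2 (1.2419e-05) and sterol sensing over both batches (9.5492e-10). None of these was called by camera, and the cause was not tested. With 3 libraries per group and the spread of batch 2, 10 of 67 simulated changes of 1.5-fold were recovered, which limits what small changes can be seen there.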

Other observations

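All tests of the resemblance to K562, the comparison of resistant 1 with K562 and the splits of the libraries were chosen after the results were seen.

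Resistant 1 was compared with K562 parental libraries in batch 1. As lists, G2 and M phase genes and monocyte markers were called higher in resistant 1 and cholesterol biosynthesis lower, and these calls were lost with an estimated correlation (adjusted p = 0.528549, 0.498205 and 0.498205). Most differences were small. Of 13006 genes tested, 4069 were higher and 3707 lower (3473 and 3476 with DESeq2), and 1248 differed by an absolute log2 fold change of 1 or more, of which 1049 were higher. The germline gene TEX19 (chromosome 17, 82359247 to 82363775) rose from 1.13 ± 0.226 to 17.8 ± 0.716 CPM (SD, n = 3; 3.97, SE 0.15, adjusted p = 2.8561e-15). The receptor gene NEO1 was higher by 3.63 (SE 0.10), TNS4 by 3.61 (SE 0.16), the fatty acid elongase gene ELOVL2 by 3.59 (SE 0.11), PAM by 3.49 (SE 0.16), GABRG1 by 3.37 (SE 0.09), HIVEP2 by 3.33 (SE 0.17) and GPR155 by 3.32 (SE 0.17). The red cell anion exchanger gene SLC4A1 was higher by 3.27 (SE 0.10), the platelet integrin gene ITGA2B by 2.39 (SE 0.08) and APOE by 1.25 (SE 0.05). The cancer-testis antigen gene CTAG2 (chromosome X, 154651972 to 154653579) differed by -4.55 (SE 0.16, adjusted p = 1.4010e-15), CD36 by -4.27 (SE 0.24), the kinesin gene KIF1A by -3.02 (SE 0.13), TSPYL6 by -2.77 (SE 0.14), COL1A2 by -2.60 (SE 0.10), SLIT2 by -2.09 (SE 0.13), RFPL4B by -1.96 (SE 0.14), PAGE1 by -1.60 (SE 0.09) and MUC19 by -1.51 (SE 0.23). The drug transporter gene ABCB1 was lower by a log2 fold change of -1.37 (SE 0.10).

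Cholesterol biosynthesis was lower in resistant 1 than in K562 as a list (adjusted p = 1.7239e-04) with 17 of 22 genes down and 2 up, or 19 and 2 when adjusted over the list alone, a median log2 fold change of -0.27 and an adjusted p = 0.498205 with an estimated correlation. CYP51A1 differed by -0.84 (SE 0.05), INSIG1 by -0.83 (SE 0.04, adjusted p = 3.6320e-13), LSS by -0.80 (SE 0.05), NPC1 by -0.43 (SE 0.05), HMGCS1 by -0.31 (SE 0.04) and SOAT1 by -0.21 (SE 0.06), while SQLE was higher (0.17, SE 0.04). SREBF2 was not called (-0.07, adjusted p = 0.186191), and was called lower without resistant 1 replicate 2 (-0.11). Inflammatory genes differed as well, with TNFAIP3 higher by 0.36 (SE 0.08) and ISG15 by 0.54 (SE 0.13). IL1B, TNF, RELB, MX1 and IFIT1 were not tested in this comparison. CXCL8 (0.70, adjusted p = 0.0335538) was not called with DESeq2 (0.68), without the low-count filter (0.68) or without K562 replicate 2 (0.64) or 3 (0.67) or resistant 1 replicate 1 (0.71) or 2 (0.60). NFKBIA (0.25, adjusted p = 0.0368104) was not called with DESeq2 (0.24) or without K562 replicate 2 (0.13) or resistant 1 replicate 2 (0.18) or 3 (0.23). G2 and M phase genes were higher (0.0135621, with 18 of 28 up and 1 down, adjusted p = 0.528549 with an estimated correlation), with NUSAP1 at 0.56 (SE 0.04). Monocyte markers were higher (0.0303684, with 8 of 11 up and 1 down, adjusted p = 0.498205 with an estimated correlation), and not without resistant 1 replicate 2 (0.0541562).

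The 9 libraries labelled resistant may hold K562 cells or cells derived from them, since the log2 fold changes of resistant 1 in batch 1 and of K562 against OCI-AML3 had an r of 0.970 across genes. A mixture with OCI-AML3 cells is argued against for all but a small share, as genes seen in OCI-AML3 but not in K562 held at most 0.227% of the vehicle level in sum. K562 parental libraries, by whose low counts these genes were chosen, held 0.0301 to 0.0348%, so a share of OCI-AML3 cells of this small size stays open. An exchange of labels in batch 1 between K562 and resistant cells that kept an OCI-AML3 profile is argued against. The libraries labelled K562 had at most r = 0.538 with OCI-AML3 libraries of that batch. An exchange between K562 and resistant cells that resemble K562 would leave this value alike and could not be seen here. The libraries labelled resistant did not keep the profile of OCI-AML3, with an r of at most 0.576 with vehicle of the same batch. This value is part of the resemblance being explained and is no separate test. An OCI-AML3 derivative that took on the whole profile was not tested, because gene counts hold no genotype. The 5 genes around MTAP had 0 counts in the libraries labelled resistant and 1 in K562. However, the block was chosen after its values were seen, and its genes were kept for their level in OCI-AML3. Counts also do not part lost DNA from silent genes. Where K562 cells would have entered was not tested either. If the libraries are of K562 origin, the comparisons with vehicle measure mainly a difference between cell lines.

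For the other counts, 10 splits of 6 libraries are too few for a share under 0.05. The real counts were 12480 for resistant 1 and vehicle in batch 1, 11521 in batch 2, 11586 for resistant 2 and vehicle, 5373 for vehicle and parental, 11820 for K562 and OCI-AML3, and 7776 for resistant 1 and K562, and the highest other split gave 0 in each. Of 40 splits drawn for each of the next counts, 1, the real one, gave as many genes. The other splits put libraries of unlike profile into the same group, which widens the spread and leaves few calls. They cannot decide the part of chance, and no conclusion is drawn from them. Resistant 1 against vehicle over both batches gave 12351 with 1 as the highest other, and the shared resistance genes numbered 8632 with 0 as the highest other.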
